A study of Mus musculus with 24 samples.

How the data were processed

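The series measured messenger RNA of mouse C57BL/6 blood progenitors on 24 short-oligonucleotide arrays of a single type, each array hybridised with 1 sample. The 24 samples fell into 7 groups by their titles: granulocyte monocyte progenitors (GMP) carrying an empty GFP vector (3 arrays), MOZ-TIF2 (4), NUP98-HOXA9 (3) or AML1-ETO (4), harvested 36 hours after infection, and sorted normal GMP (4), sorted normal LSK cells (3, titled HSC) and MOZ-TIF2 leukemic GMP (3). The labels do not say whether replicates were separate animals, cultures or infections. The p-values therefore measure the spread between these samples, which may be partly technical.

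The deposited table holds log2 expression estimates made by the authors with GCRMA 2.4.1 from the cell intensity files of the MAS5 software, per the submitters' processing notes and the series design text. GCRMA corrects background by probe sequence and normalizes arrays to each other. The values ran from 1.72 to 14.39 with array medians of 5.63 to 5.76, so no further log was taken and no further normalization was applied. Per the series design text the authors also removed arrays of poor quality, and kept genes by a level over 60 together with present calls. Which arrays they removed is not given in the sources used here, and the present calls were not used here.

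The table had 22690 probe sets, of which 64 control probe sets were left out. Of the other probe sets, 20380 carried 1 gene symbol, 691 carried several and 1555 carried none in the platform annotation used. Symbols were looked up through gene identifiers in a RefSeq gene table, which matched 20351 probe sets and changed 0 symbols. The named probe sets stood for 12393 genes. Genes were named only from probe sets with 1 symbol, and where a gene had several probe sets, its values come from the probe set with the highest mean over the 24 arrays. A gene was counted as past the threshold when at least 1 of its probe sets passed.

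Each comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on the deposited log2 values. Probe sets were tested where the linear value was over 60 (5.91 on the log2 scale) on at least 2 arrays of at least 1 compared group, with Benjamini-Hochberg adjustment and a threshold of 0.05. The two-class comparisons used only the arrays of the classes named: all oncogenes against GFP, each oncogene against GFP, LSK against GMP, leukemic GMP against GMP, and GFP GMP against GMP. The differences between oncogenes were contrasts in a fit to the 14 transduced arrays with 1 mean per group. Where every array of a group was under 60, or its mean was, a fold was given only as a lower bound, the mean of the other group against 60. The number of arrays limits the precision.

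The design's initiation program was rebuilt as probe sets called with the same sign in all oncogenes against GFP and in LSK against GMP, and overlaps were tested with Fisher's exact test, two-sided. Fold changes of comparisons that share control arrays were set beside the same measure in simulated unchanged groups against those controls.

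Groups of genes were tested with camera of limma (preset correlation 0.01, lists with at least 5 tested genes, adjustment over the lists of a comparison). The 24 lists held 628 genes, 556 of them on the array: LSK stem cell, Hoxa cluster and cofactors, primary granule, secondary granule and neutrophil maturation, monocyte and macrophage, myeloid transcription factors, Wnt and beta-catenin targets, ribosome biogenesis and Myc targets, S phase, G2 and mitosis, interferon response, NF-kB and inflammatory, p53 targets, JAK-STAT cytokine targets and receptors, cholesterol biosynthesis, glycolysis and hypoxia, immediate early and stress, ATF4 and unfolded protein response, megakaryocyte and erythroid, lymphoid, mast cell with basophil and eosinophil, dendritic cell and MHC class II, oncogene partner genes, and sex-linked.

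The genes named follow a rule. For the comparisons of the design text, these are the 8 largest increases and 8 largest decreases among genes past the threshold whose classes do not overlap on any array (4 and 4 for the other comparisons). To these come up to 4 members with the smallest adjusted p of each list that passed the list test or had at least 25% of its members past the threshold, the oncogene partner genes everywhere, and the 8 higher and 8 lower program genes with the largest smaller change. Counts of named genes below cover all genes picked in these ways, some of which are not printed. Any other gene was chosen after its values were seen and is named as such or as a member of a small count. This rule, the lists, the designs and the alternatives were fixed before the data were examined. The way of joining the 3 oncogenes by their group means, and the rebuilding of the program at unadjusted p, were chosen after seeing the data.

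File names carry a tag that splits the arrays: all GFP arrays have tag A. Tag A also covers MOZ-TIF2 arrays 1 to 3, NUP98-HOXA9 arrays 1 and 2, AML1-ETO array 1, LSK arrays 1 and 2, GMP arrays 1 to 3 and leukemic GMP array 1. AML1-ETO arrays 2 to 4, MOZ-TIF2 array 4 and GMP array 4 have tag B, and the others have none. What the tag means is not given in the sources used here, so it was treated as a possible batch.

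Alternatives were no filter, all 24 arrays in 1 fit with and without the tag as a factor, Welch's unequal-variance test with the same adjustment (the test of the design text), the replicate number as a block, tag A arrays alone, the letter or number that opens the file name as a block, quantile normalization, values under 60 raised to 60, array weights, a trended robust variance, leaving out each array in turn, and for the lists an estimated correlation and the mean of a gene's probe sets. The replicate numbers were not taken as pairs, since in each comparison at least 1 pair of same-numbered arrays had a correlation of deviations under 0.1. Single pairs ran from −0.437 to 0.487 for NHA9 against AE and from −0.192 to 0.278 for GFP GMP against GMP. For MT2 against GFP 2 of 3 arrays went best with their own number, so a pairing of some arrays is not excluded. Array quality was checked with control probe sets, sex-linked genes, medians, shares over 60 and principal components. The fits and the list test were tried on simulated data, drawn as independent normal noise with each probe set's SD within groups. With changes added, the fit for all oncogenes recovered 82% of changes of 1 on the log2 scale and 99% of changes of 2. There the 11 oncogene arrays were drawn as 1 uniform class, without differences between oncogenes or tags. These shares therefore do not carry over to the real all-oncogene comparison. For MOZ-TIF2 against GFP these shares were 58% and 95%, for NUP98-HOXA9 37% and 99%, and for AML1-ETO 65% and 98%. They were 56% and 97% for LSK, 54% and 94% for leukemic GMP, and 60% and 95% for GFP against GMP. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.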

Results

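Gene expression was measured in mouse bone marrow progenitors on 24 arrays in 7 groups. GMP, the progenitors of neutrophils and monocytes, were infected with a GFP vector alone (3 arrays), with MOZ-TIF2 (MT2, 4), with NUP98-HOXA9 (NHA9, 3) or with AML1-ETO (AE, 4), and GFP-positive cells were harvested 36 hours later. These fusion oncogenes occur in acute myeloid leukemia. The other groups were sorted normal GMP (4 arrays), sorted normal LSK cells (3), which hold the blood stem cells, and GMP from MT2 leukemias (L-GMP, 3). Values are log2 expression with the SD over arrays, and log2 differences carry their standard error (SE) and the adjusted p of limma. On each array 46.1% to 48.3% of probe sets lay over the background level of 60.

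The first principal component held 36.8% of the variance and set the transduced groups apart from the fresh ones. MT2 arrays lay between 6.79 and 19.2 on it, while GFP arrays lay between 26.6 and 28.0 and normal GMP between −36.1 and −29.0. The third component placed GMP 2 at −56.6, away from the other GMP arrays. L-GMP 1 lay at 18.6 on the second component (14.6%), against 49.8 and 48.0 for the other L-GMP arrays. L-GMP 1 also had the highest 3' minus 5' signal of all arrays for Gapdh (4.82) and actin (3.45), a measure of RNA quality, and whether this bears on the calls lost without it was not tested. On L-GMP 2 these were 3.58 and 2.43, and on L-GMP 3 3.08 and 2.66.

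**Figure D1:**
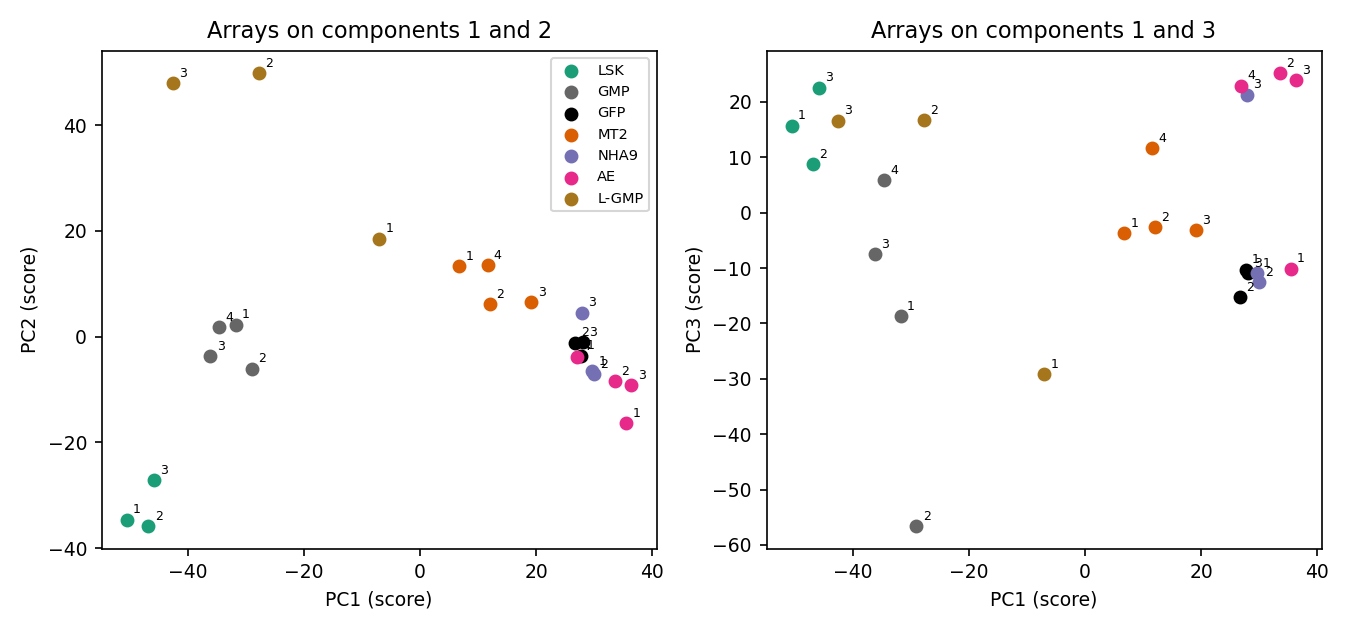
Arrays on principal components 1 and 2 (left) and 1 and 3 (right), in score units, coloured by group and numbered by replicate. Component 1 parts the transduced groups (right) from LSK, GMP and L-GMP (left), and GMP 2 stands apart at −56.6 on component 3.

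All oncogenes against GFP asked which changes the 3 oncogenes share. With the 11 oncogene arrays as 1 class, no gene passed. Hoxa9, a homeobox gene of stem cells and a partner in NUP98-HOXA9, stood at 10.03 ± 1.07 (SD, n = 11) against 9.19 ± 0.26 (n = 3), a difference of 0.84 (SE 0.56, adjusted p = 0.575). Runx1, the mouse gene of AML1, differed by 0.49 (SE 0.24, adjusted p = 0.477), Kat6a, that of MOZ, by 0.01 (adjusted p = 0.989), and Nup98 by 0.12 (adjusted p = 0.754).

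No member of any list passed, and 6 lists passed camera with the preset correlation but none with an estimated one. The median of all genes was 0.08. Among 30 S phase genes, which serve DNA replication, 27 lay lower, with a median of −0.28 (camera adjusted p = 9.39e-10, or 0.694 with an estimated correlation). For 34 genes of G2 and mitosis the median was −0.17 (camera adjusted p = 2.41e-07, or 0.694 estimated). Genes of primary granules, made early in neutrophil development, had a median of −0.26 (16 genes, camera adjusted p = 7.31e-05, or 0.146 estimated), and those of secondary granules and neutrophil maturation −0.38 (20 genes, 5.48e-05, or 0.694 estimated). Cholesterol biosynthesis lay lower as well (19 genes, median −0.17, camera adjusted p = 0.0012, or 0.694 estimated), while the interferon response lay higher (28 genes, median 0.25, 0.025, or 0.753 estimated). Adjusted over the list alone, 0 members were called in these lists except 1 lower S phase gene. The LSK stem cell list (17 genes, median 0.42, camera adjusted p = 0.257) and the Hoxa cluster and cofactors (7 genes, median 0.44, 0.357) did not pass. Within tag A the Hoxa list passed as higher (0.0442), as did ribosome biogenesis and Myc targets (2.16e-04), and glycolysis and hypoxia passed as lower (8.89e-04, and 0.0318 without NHA9 1).

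limma called 0 of 11632 probe sets, with 1250 at an unadjusted p under 0.05, or 10.7% where 5% is expected by chance. The test of the design text called 116 probe sets (97 genes). The fit left the count at 0 without any 1 array and within tag A. The difference between oncogenes enters the spread of the joined class. Joined instead as the mean of the 3 group means in the 14 transduced arrays, a choice made after seeing the data, 217 probe sets passed, 186 higher and 31 lower. The design text gives 1082 genes for this comparison, with present calls and an exclusion of arrays that were not used here.

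MT2 against GFP asked what MOZ-TIF2, a fusion of a histone acetyltransferase with a coactivator, does alone. Sox4, Rgs18 and Hoxa9 were among the higher genes, and Mycn and S100a9 among the lower ones. Sox4, a transcription factor of progenitors, stood at 8.54 ± 0.48 (SD, n = 4) against 5.27 ± 0.57 (n = 3), at least 6.2-fold higher (log2 difference 3.27, SE 0.29, adjusted p = 0.00182). Hoxa9 rose 2.83-fold to 10.69 ± 0.46 (SE of the log2 difference 0.23, adjusted p = 0.00853), and its cofactor gene Meis1 rose at least 1.29-fold (log2 2.19, SE 0.37, adjusted p = 0.0104). Rgs18, which dampens G protein signalling in blood cells, rose 4.64-fold (log2 2.21, SE 0.17, adjusted p = 0.000929). Igf2bp3, an RNA-binding protein of fetal cells, rose at least 1.84-fold (adjusted p = 0.00572). Bex6, the gap junction gene Gja1 and Parp8 rose by log2 1.96, 1.63 and 1.56, and Bex1 at least 3.55-fold.

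Mycn, a Myc family gene, showed the largest decrease named: 10.57 ± 0.60 against 13.41 ± 0.27, 7.12-fold lower (log2 −2.83, SE 0.28, adjusted p = 0.00299). S100a9, an abundant neutrophil protein, was 3.55-fold lower (log2 −1.83, SE 0.37, adjusted p = 0.0163), and the granule gene Pglyrp1 fell by log2 1.81 (SE 0.36). Fn1, Psg28, the decoy receptor gene Il1r2 and Sema4a changed by log2 −2.34, −2.03, −1.86 and −1.71. Gm9222 was at least 1.97-fold lower. Runx1 (0.30, adjusted p = 0.196), Kat6a (−0.21, 0.262) and Nup98 (0.10, 0.587) did not pass.

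Of 33 ribosome biogenesis and Myc target genes, 28 rose and 1 fell (31 and 1 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 1.66e-15, or 0.522 with an estimated correlation). Its members Srm, Nop2, Gnl3 and Pus7 rose by log2 1.08, 1.00, 0.95 and 1.29, and Myc itself rose 2.06-fold (adjusted p = 0.00845). Of 19 secondary granule and neutrophil maturation genes, 11 fell and 0 rose (16 adjusted over the list alone), with a median of −0.998 (camera adjusted p = 4.74e-11, or 0.522 estimated). Lcn2 was 2.17-fold (adjusted p = 0.00873) and Anxa1 2-fold lower (0.0127). In glycolysis and hypoxia, 4 of 25 genes fell, namely Slc2a1, Pfkl, Aldoc and Ndrg1 (5 adjusted over the list alone), with a median of −0.35 (camera adjusted p = 1.25e-05, or 0.554 estimated). G2 and mitosis (34 genes, 0 called, also over the list alone) had a median of −0.22 (camera adjusted p = 1.19e-05, or 0.554 estimated). Cholesterol biosynthesis (19 genes, 0 called, also over the list alone) had a median of −0.23 (0.00171, or 0.554 estimated). Immediate early and stress genes (18) had 1 decrease, Klf2 (3 adjusted over the list alone), and a median of −0.20 (0.00985, or 0.554 estimated). S phase lay lower by a median of −0.07 (camera adjusted p = 0.0302, or 0.604 estimated), with Rrm2 and Ccne2 lower and Gins1 higher, the same numbers over the list alone. NF-kB and inflammatory genes (16, median −0.16) had 1 decrease, Nfkbia, also over the list alone, and a camera adjusted p of 0.0406 (0.554 estimated, 0.0614 within tag A, 0.0752 after quantile normalization, 0.0542 with the mean of probe sets).

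Lists that did not pass still held called members. In the LSK stem cell list (16 genes, median 0.27, camera adjusted p = 0.416) Lmo2, Tal1, Etv6 and Meis1 rose and Mycn fell (6 and 1 adjusted over the list alone). Of 20 myeloid transcription factors 5 rose, among them Zeb2 (0.95), Mef2c (0.97) and Etv6 (0.83), and Id2 fell by log2 1.57. The count over the list alone was 6 and 5, with a camera adjusted p of 0.416. In the ATF4 and unfolded protein response 5 of 28 genes rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.133), namely Aldh18a1, Phgdh, Psat1, Shmt2 and Slc7a11, and in the interferon response 4 of 27, namely Gbp3, Ifi47, Oas1a and Psmb8 (6 over the list alone, 0.0671, and 0.0499 after quantile normalization). Prg2, an eosinophil granule gene, was at least 1.72-fold lower (adjusted p = 0.0396).

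limma called 1316 probe sets for MT2 (994 genes), 990 higher and 326 lower, or 75.2% higher, and after quantile normalization 700 higher and 517 lower, or 57.5%. The unadjusted p was under 0.05 for 3315 of 11113 probe sets. By the test of the design text 0 passed adjustment, and 1862 genes had an unadjusted p under 0.05, where the design text gives 5750 genes. Within tag A 879 were called. The count fell to 568 without MT2 1, 536 without GFP 1, 170 without GFP 2 and 696 without GFP 3. Of the 41 named genes past the threshold, 19 kept the call with each array left out in turn and 36 within tag A; without GFP 2 it was 20. With the tag as a factor over all 24 arrays 22 kept it. The granule and neutrophil genes S100a9, Pglyrp1, Lcn2 and Anxa1 were among those that lost it there, and all but Lcn2 also lost it without GFP 2. Sox4, Rgs18, Hoxa9 and Mycn kept the call in these fits.

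**Figure D2:**
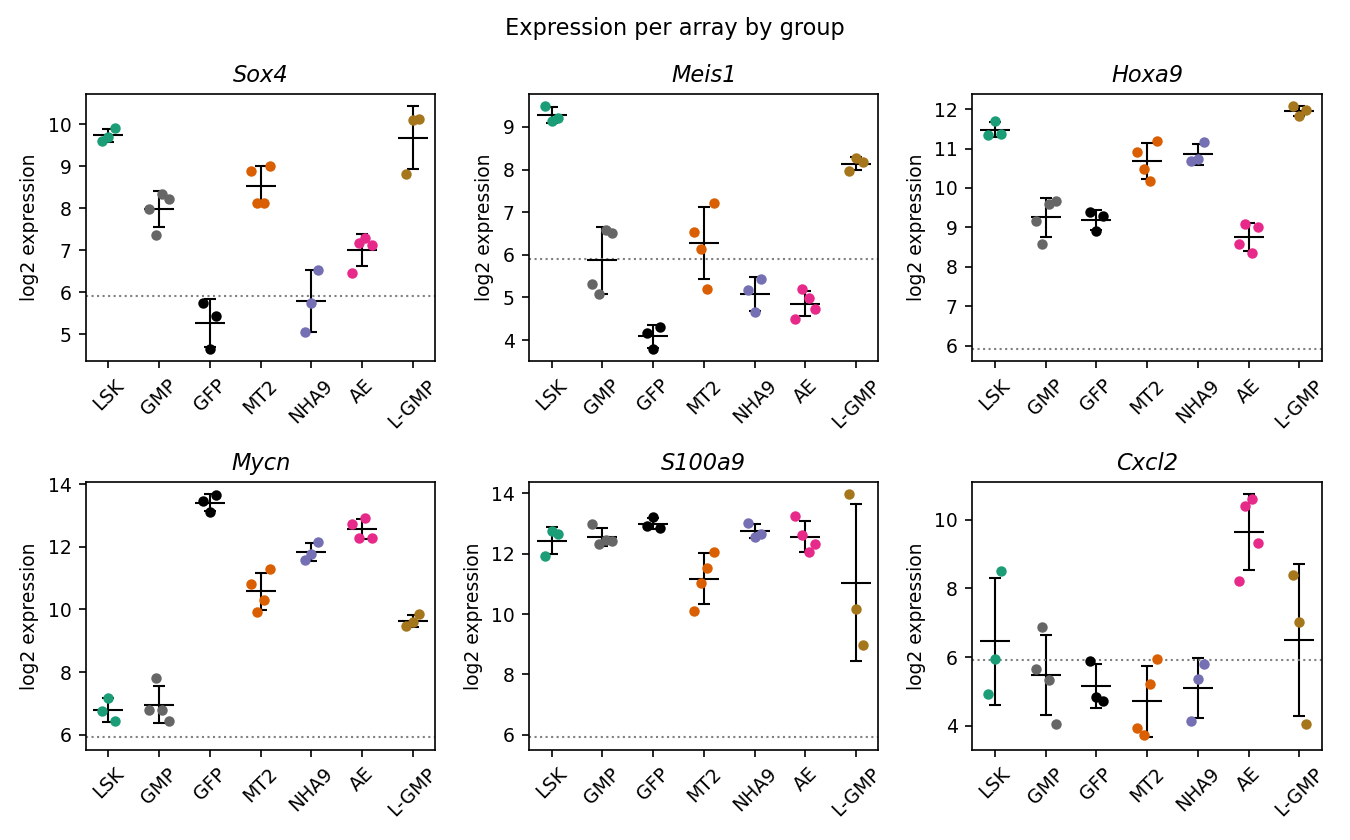
Log2 expression of 6 genes on each array (points) by group, with the group mean and SD (bars); the dotted line is the background level of 60. In Sox4 the 4 MT2 arrays lie above the 3 GFP arrays, in Mycn all oncogene arrays lie below them, and Cxcl2 is over background on all 4 AE arrays.

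NHA9 against GFP asked the same of NUP98-HOXA9, a fusion of a nuclear pore protein with a homeodomain. Hoxa5 had the largest increase among the genes named. Hoxa5 stood at 7.94 ± 0.12 (SD, n = 3) against 5.46 ± 0.20 (n = 3), at least 4.08-fold higher (log2 difference 2.48, SE 0.15, adjusted p = 0.00111). Hoxa9 rose 3.18-fold to 10.86 ± 0.26 (log2 1.67, SE 0.19, adjusted p = 0.0272), and whether the probe set also reads the HOXA9 part of the vector was not tested. Mef2c, a transcription factor of progenitors, rose 3.04-fold (log2 1.60, SE 0.16, adjusted p = 0.0178). The costimulator Cd28 rose at least 1.51-fold and Frmd4b at least 1.26-fold. Tspan13, Olfm1 and the receptor gene Calcrl rose by log2 1.30, 1.24 and 1.22. Mycn was the single gene that fell, from 13.41 ± 0.27 to 11.84 ± 0.30 (log2 −1.57, SE 0.20, adjusted p = 0.0283). Runx1 (0.39, adjusted p = 0.559), Kat6a (0.12, 0.735) and Nup98 (−0.10, 0.791) did not pass.

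The Hoxa cluster and cofactors lay higher (6 genes, 2 rose, 3 adjusted over the list alone, median 0.34, camera adjusted p = 9.79e-04, or 0.172 with an estimated correlation). Monocyte and macrophage genes had a median of 0.36 (24 genes, 0 called, 5 higher adjusted over the list alone, 2.94e-04, or 0.339 estimated). For dendritic cell and MHC class II genes it was 0.43 (9 genes, 0 called, 4 higher over the list alone, 0.00172, or 0.172 estimated). NF-kB and inflammatory genes had a median of 0.28 (15 genes, 0 called, 3 higher over the list alone, 0.0126, or 0.223 estimated), and interferon response genes 0.20 (21 genes, 0 called, 5 higher over the list alone, 0.0402, or 0.572 estimated). Primary granule genes lay lower with a median of −0.27 (16 genes, 0 called, also over the list alone, 4.6e-06, or 0.172 estimated). So did S phase (30 genes, −0.15, 1.7e-04, or 0.532 estimated) and cholesterol biosynthesis (19 genes, −0.28, 2.94e-04, or 0.572 estimated), each with 0 members called, also over the list alone. The secondary granule list (median 0.17, camera adjusted p = 0.598) and the ribosome biogenesis and Myc target list (median 0.12, 0.299) did not pass. Lists that passed only in other settings were Wnt and beta-catenin targets, higher after quantile normalization (0.0485) and without NHA9 1 (0.041), and within tag A JAK-STAT, higher (0.0345), and G2 and mitosis, lower (0.0152).

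limma called 22 probe sets for NHA9 (18 genes), 21 higher and 1 lower, with 1154 of 10981 at an unadjusted p under 0.05. By the test of the design text 0 passed, and 691 genes had an unadjusted p under 0.05, where the design text gives 1161 genes. The count rests on single arrays: it was 1 without NHA9 1, NHA9 2 or GFP 3, 2 without GFP 1 or GFP 2, and 202 without NHA9 3, where 119 were lower and 83 higher. Within tag A 196 were called, 81 higher and 115 lower. Of the 9 named genes past the threshold, 1 (Hoxa5) kept the call with each array left out in turn, all 9 kept it within tag A, and 3 (Hoxa5, Hoxa9 and Cd28) kept it with the tag as a factor over all 24 arrays.

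AE against GFP asked the same of AML1-ETO, a DNA-binding factor fused to a corepressor. Serpinb2, Cxcl2 and Arg1 were among the higher genes, and Itgb2 and Cebpa among the lower ones. Serpinb2, a protease inhibitor of activated monocytes, stood at 9.00 ± 1.55 (SD, n = 4) against 3.12 ± 0.25 (n = 3), at least 8.55-fold higher (log2 difference 5.89, SE 0.67, adjusted p = 0.00154). The chemokine gene Cxcl2 rose at least 13.3-fold to 9.64 ± 1.10 (log2 4.49, SE 0.53, adjusted p = 0.00176). Arg1, an arginase of macrophages, rose 11.7-fold to 12.04 ± 0.57 (log2 3.54, SE 0.41, adjusted p = 0.00173). Of the protease inhibitor genes, Ctla2a rose at least 11.7-fold and Ctla2b rose 14.9-fold. The platelet chemokine genes Ppbp and Pf4 rose 21.5-fold and 8.71-fold, and the adaptor gene Dab2 8.28-fold. Itgb2, the shared chain of the leukocyte integrins, fell 3.97-fold to 8.23 ± 0.33 (log2 −1.99, SE 0.19, adjusted p = 0.00115). The adhesion receptor gene Adgre5 was 3.99-fold lower. Ifitm6, Cd244a, Ffar2, Itgb7, the transferrin receptor gene Tfrc and Arhgef18 changed by log2 −2.36, −1.86, −1.77, −1.75, −1.66 and −1.65. Cebpa, the transcription factor that drives GMP formation, fell 2.72-fold to 7.64 ± 0.47 (log2 −1.44, SE 0.24, adjusted p = 0.00669). Cd34 of early progenitors rose 3.94-fold (log2 1.98, SE 0.24, adjusted p = 0.00192). Runx1 (0.75, adjusted p = 0.101), Hoxa9 (−0.44, 0.215), Nup98 (0.30, 0.182) and Kat6a (0.14, 0.614) did not pass.

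Quantile normalization moved the median of all genes for AE from 0.10 to −0.01. The list medians that follow are given without subtracting that 0.10 and should be read against it. Values within tag A rest on AE 1 as the only AE array, with the spread taken from the GFP arrays. S phase lay lowest: 6 of 30 genes fell, Mcm4, Mcm6, Dut and Rrm2 among them (13 adjusted over the list alone), with a median of −0.55 (camera adjusted p = 5.23e-12, or 0.535 with an estimated correlation). In G2 and mitosis (34 genes, median −0.24) Mki67 and Top2a fell (0 over the list alone, camera adjusted p = 1.33e-05, or 0.535 estimated). Immediate early and stress genes, which answer signals within minutes, had 10 of 22 members higher (12 over the list alone) and a median of 0.90 (3.59e-04, or 0.535 estimated). Klf6 rose 3.05-fold, Ier2 2.15-fold and Ppp1r15a 1.96-fold. Of 18 NF-kB and inflammatory genes 9 rose and 2 fell (10 and 3 over the list alone), with a median of 0.70 (0.0116, or 0.535 estimated). Relb rose at least 3.53-fold, Icam1 3.63-fold and Tnip1 2.1-fold. JAK-STAT cytokine targets and receptors had 4 of 17 members higher (7 and 1 lower over the list alone) and a median of 0.53 (0.0352, or 0.535 estimated, 0.0675 within tag A). These were Gadd45g (6.34-fold), Spred1, Il7r (at least 1.15-fold) and Spry2.

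Primary granule genes (16, median −0.26, camera adjusted p = 0.00158, or 0.535 with an estimated correlation) had 4 decreases and 1 increase, the same over the list alone. Elane, Gstm1 and Ms4a3 changed by log2 −1.03, −1.17 and −1.13, and Lyz2 rose by 0.76. Il1r2 and Anxa1 fell in the secondary granule and neutrophil maturation list (20 genes, 2 over the list alone, median −0.38, 0.0177, or 0.535 estimated, 0.0675 within tag A, 0.0762 after quantile normalization). The ribosome biogenesis and Myc target list (32 genes, median −0.15) had Ipo4 higher and Tfrc lower (0 and 1 over the list alone, 0.00945, or 0.739 estimated). In the ATF4 and unfolded protein response (28 genes, median −0.27) Slc7a11 and Xbp1 rose and Sdf2l1 fell, the same numbers over the list alone (0.0352, or 0.586 estimated, 0.0675 within tag A, 0.0767 after quantile normalization). Lists that did not pass included LSK stem cell (16 genes, 3 higher, 1 lower, 8 and 1 over the list alone, median 0.50, camera adjusted p = 0.109, and 0.0477 after quantile normalization). There Cd34, Rbpms and Bmi1 rose and Mycn fell by log2 0.85. Among 9 Wnt and beta-catenin targets Sox4 (at least 2.15-fold), Ptger2 and Jun (3.78-fold) rose, the same over the list alone (0.109, and 0.0477 after quantile normalization). Myeloid transcription factors split, with Jun, Egr2 and Id1 higher and Cebpa, Gfi1 and Klf4 lower (7 and 5 over the list alone, 0.857). Megakaryocyte and erythroid genes split too, with Pf4, Ppbp and Cd36 higher and Nfe2 lower by log2 1.52, the same numbers over the list alone (0.857). The mast cell genes Hdc and Cpa3 rose by log2 1.54 and 1.73 in a list of 4, too few to test. The lymphoid gene Cd79b rose by log2 1.29 in a list of 6 whose median was 0.00, mean 0.27 and test direction down (camera adjusted p = 0.896).

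limma called 1249 probe sets for AE (991 genes), 997 higher and 252 lower, or 79.8% higher, and after quantile normalization 689 higher and 468 lower, or 59.6%. The unadjusted p was under 0.05 for 3241 of 11393. By the test of the design text 0 passed, and 2077 genes had an unadjusted p under 0.05, where the design text gives 5109 genes. All GFP arrays and AE 1 have tag A while AE 2 to 4 have tag B. Over all 24 arrays in 1 fit, 1259 were called, 1000 higher, and 969 of the 1249 stayed. With the tag as a factor the larger side turned: 1309 were called, 559 higher and 750 lower, and 653 stayed. Within tag A AE is a single array with its spread taken from GFP, so that fit describes AE 1 and is no check of the group. The count was 3061 without AE 1, 705 without AE 2, 739 without AE 3, 447 without GFP 1, 329 without GFP 2 and 722 without GFP 3. Of the 57 named genes past the threshold, 31 kept the call with each array left out in turn and 39 with the tag as a factor.

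**Figure D3:**
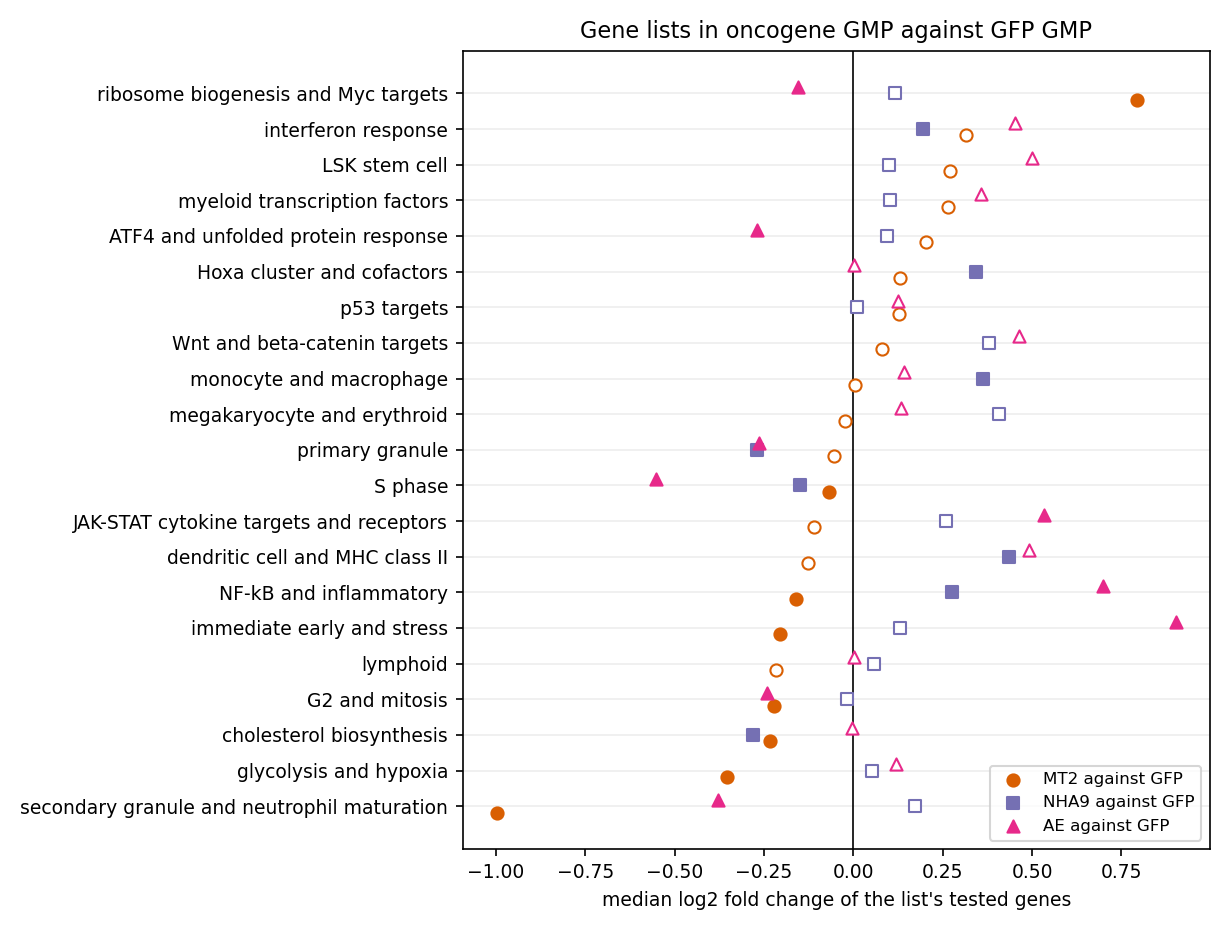
Median log2 fold change of each tested gene list in MT2, NHA9 and AE GMP against GFP GMP. Filled symbols passed camera with the preset correlation, open ones did not, and none passed with an estimated correlation; ribosome biogenesis and Myc targets pass as higher for MT2 alone, and S phase medians are below 0 for each oncogene.

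The differences between oncogenes were tested directly. MT2 against NHA9 gave Sox4 at least 6.2-fold higher for MT2 (8.54 ± 0.48 against 5.78 ± 0.74; log2 difference 2.76, SE 0.35, adjusted p = 0.00108) and Rgs18 4.28-fold higher. Igf2bp3 was at least 1.84-fold and Ankrd28 2.83-fold higher. Arg1 was at least 16.2-fold lower (log2 −4.04, SE 0.71, adjusted p = 0.00518), Fn1 6.76-fold lower, Cd244a 6.33-fold lower and Myl10 at least 2.59-fold lower. Ribosome biogenesis and Myc targets were higher for MT2 (33 genes, 14 called, 25 adjusted over the list alone, median 0.64, camera adjusted p = 1.57e-14, or 0.278 with an estimated correlation), with Ddx21, Srm and Bop1 at 1.09, 0.94 and 0.79. Secondary granule genes were lower (20 genes, 11 called, 18 over the list alone, median −1.13, 6.62e-12, or 0.116 estimated), with Il1r2, Padi4, Ltb4r1 and Lcn2 at −2.26, −1.59, −1.18 and −0.85. NF-kB (18 genes, 4 called, 7 over the list alone, −0.42, 6.3e-05, or 0.116 estimated) included Nfkbia, Bcl3 and Ccl3 at −1.02, −0.94 and −1.87. Monocyte and macrophage (25 genes, 2 called, 9 over the list alone, −0.65, 1.23e-05, or 0.333 estimated) included Lgals3. Glycolysis and hypoxia (25 genes, 5 called, 7 over the list alone, −0.53, 7.06e-05, or 0.372 estimated) included Ndrg1 and Aldoc. Dendritic cell and MHC class II (10 genes, 2 called, 4 over the list alone, −0.69, 4.42e-04, or 0.146 estimated) included H2-Oa. Immediate early genes (22, 4 called, 6 over the list alone, −0.31, 0.003, or 0.542 estimated) included Mcl1. G2 and mitosis (34 genes, 0 called, also over the list alone, −0.24, 0.00575, or 0.658 estimated) did not pass within tag A (0.295). JAK-STAT passed only without NHA9 1, as lower (0.0402). Hoxa9 did not differ past the threshold (−0.17, adjusted p = 0.746), nor did Runx1 (−0.09), Kat6a (−0.33) or Nup98 (0.19). Of 11632 probe sets 828 passed, 375 higher and 453 lower for MT2. The larger side turned within tag A, where 1376 of 2091 were higher and 715 lower, and without NHA9 3, where 681 were higher and 356 lower. The count was 304 without MT2 1, 465 without MT2 4, 221 without NHA9 1 and 397 without NHA9 2. Of the 35 named genes past the threshold, 19 kept the call with each array left out.

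MT2 against AE gave the most calls. Arg1 was at least 70.1-fold lower for MT2 (5.88 ± 1.76 against 12.04 ± 0.57; log2 difference −6.16, SE 0.66, adjusted p = 2.67e-05), Ppbp 31.4-fold lower, and Cxcl2 at least 13.3-fold and Serpinb2 at least 8.55-fold lower. The cystathionine lyase gene Cth was 6.83-fold higher (adjusted p = 0.000107), Bex6 at least 5.9-fold, Rgs18 6.08-fold and Chdh 4.8-fold. Hoxa9 was 3.82-fold higher (log2 1.93, SE 0.23, adjusted p = 4.81e-05), Cebpa 3.27-fold higher (2.67e-05) and Sox4 2.89-fold higher (0.00303). Of 33 ribosome biogenesis and Myc target genes 30 were higher (31 adjusted over the list alone, median 0.92, camera adjusted p = 8.13e-17, or 0.322 with an estimated correlation), with Gnl3 at 1.31. Of 30 S phase genes 13 were higher (17 over the list alone, 0.46, 4.52e-07, or 0.425 estimated), with Mcm6 at 0.99. Of 28 ATF4 genes 11 were higher and 3 lower (12 and 3 over the list alone, 0.35, 0.00347, or 0.425 estimated). Immediate early genes were lower in 14 of 22 (16 over the list alone, −1.03, 3.1e-07, or 0.322 estimated), with Klf6 at −2.12 and Jun at −2.50. NF-kB genes were lower in 10 of 18 and higher in 1, the same over the list alone (−0.87, 1.63e-04, or 0.177 estimated), with Icam1 at −2.02. Glycolysis and hypoxia genes were lower in 10 of 25 (14 lower and 1 higher over the list alone, −0.63, 9.74e-04, or 0.425 estimated). Secondary granule genes were lower in 10 of 20, also over the list alone (−0.67, 0.00314, or 0.425 estimated), with Lcn2 at −1.60. Dendritic cell and MHC class II genes were lower in 5 of 10, also over the list alone (−0.66, 0.0256, or 0.397 estimated). JAK-STAT genes were lower in 8 of 17 and higher in 1, the same over the list alone (−0.39, 0.0302, or 0.353 estimated, 0.132 within tag A, where AE is 1 array). Of 11632 probe sets 3227 passed, 1392 higher and 1835 lower for MT2, and without AE 4 1659 higher and 1648 lower. Within tag A, with 1 AE array, more were higher. Of the 78 named genes past the threshold, 72 kept the call with each array left out.

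NHA9 against AE gave Hoxa5 at least 4.08-fold (log2 difference 2.12, SE 0.21, adjusted p = 0.000105) and Hoxa9 4.29-fold higher for NHA9 (log2 2.10, SE 0.25, adjusted p = 0.000194). Apoc2 was 5.9-fold higher (0.000151), and Cd244a, Ifitm6 and Itgb7 were higher by log2 2.84, 2.16 and 2.12. Serpinb2 was at least 8.55-fold, Cxcl2 at least 13.3-fold and Ctla2a at least 11.7-fold lower, and Ctla2b lower by log2 −3.56. S phase genes were higher for NHA9 in 4 of 30, also over the list alone (median 0.39, camera adjusted p = 7.3e-09, or 0.559 with an estimated correlation), with Cdc45 at 1.05. Ribosome biogenesis and Myc target genes (33, 0 called, also over the list alone, 0.28, 5.05e-05, or 0.559 estimated) and G2 and mitosis (34 genes, Mki67 called, 0 over the list alone, 0.26, 1.59e-04, or 0.559 estimated, 0.438 within tag A) were higher. Immediate early genes were lower in 9 of 22 (12 over the list alone, −0.78, 9.86e-05, or 0.559 estimated), with Klf6 at −1.62. Calls not held within tag A, where AE is 1 array, were Hoxa (7 genes, 3 higher, 3 and 1 over the list alone, 0.24, 0.00464, or 0.407 estimated, 0.0733 within tag A), secondary granule (20 genes, 3 higher and 1 lower, 4 and 1 over the list alone, 0.49, 0.00632, or 0.559 estimated, 0.133 within tag A) and LSK stem cell (17 genes, 4 lower, 1 and 9 over the list alone, −0.52, 0.0172, or 0.559 estimated, 0.189 within tag A). ATF4 genes (28, 2 higher and 2 lower, 5 and 2 over the list alone, 0.21, 0.00607, or 0.559 estimated) and monocyte genes (25, 1 higher and 1 lower, 5 and 1 over the list alone, 0.34, 0.0313, or 0.685 estimated, 0.102 after quantile normalization) were higher. The mast cell genes Hdc and Cpa3 were lower by log2 −2.45 and −1.76. Of 11632 probe sets 813 passed, 296 higher and 517 lower for NHA9. Within tag A, with 1 AE array, more were higher. Lists that passed only in other settings were NF-kB, lower with the mean of probe sets (0.0212) and within tag A (0.0218), and cholesterol biosynthesis, lower within tag A (0.0324). The count was 388 without NHA9 1, 431 without NHA9 2, 1372 without AE 1 and 488 without AE 3. Of the 41 named genes past the threshold, 22 kept the call with each array left out.

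Fold changes against the same GFP arrays were compared across genes, which are not independent replicates. For MT2 and AE, Pearson r was 0.198 over 6879 genes, where simulated unchanged groups against the shared controls gave 0.572. The covariance was 0.0316 against a simulated 0.0332. For NHA9 and AE r was 0.541 (simulated 0.531) and the covariance 0.0663 (simulated 0.0328). For MT2 and NHA9 r was 0.251 (simulated 0.531) and the covariance 0.0231 (simulated 0.0326). GFP arrays were the most alike, so simulated covariances (SD over all groups) may be too large. Mycn alone was called for all 3 oncogenes, lower each time, but for NHA9 and for AE the call was lost in 5 of the fits with 1 array left out, including without each GFP array. Higher for both MT2 and AE were 58 genes, where independent lists give 50.4 (Fisher's exact p = 0.248), and lower for both were 42, where they give 5.63 (Fisher's exact p = 6.11e-26). The GFP group has too few arrays to split, and part of the excess may come from the shared controls. So may the same direction for NHA9, where 51 of the 53 higher genes with a value were over 0. Of the 42, 23 were under 0 for NHA9.

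LSK against GMP served the design as a filter for genes of self-renewing cells, and asked what changes between stem cell fraction and GMP. Hlf, a transcription factor of stem cells, stood at 9.81 ± 0.23 (SD, n = 3) against 6.22 ± 0.35 (n = 4), 12.1-fold higher (log2 difference 3.60, SE 0.22, adjusted p = 2.76e-05). Procr, a stem cell surface receptor, rose at least 7.26-fold (log2 4.53, SE 0.30, adjusted p = 4.3e-05). Meis1 was at least 10.3-fold higher at 9.28 ± 0.19 and Hoxa9 4.67-fold higher at 11.48 ± 0.20 (adjusted p = 0.000679 and 0.00106). The cytokine receptor gene Flt3 was 9.25-fold higher (log2 3.21, SE 0.31, adjusted p = 0.000408). The lymphoid enzyme gene Dntt was at least 14.1-fold higher, Gcnt2 at least 15-fold and Tgm2 at least 12.3-fold. Ctla2a was 17.4-fold and Rgs1 17-fold higher. The germ cell gene Ddx4 was at least 2.81-fold and Ltb at least 10.7-fold higher. Among the lower genes, Fcgr3, a receptor used to sort GMP, stood at 6.65 ± 0.60 against 9.32 ± 0.11, 6.36-fold lower (log2 −2.67, SE 0.25, adjusted p = 0.000383). Ctsg, a granule protease, was 4.21-fold lower at 11.16 ± 0.51 (adjusted p = 0.000647). Ms4a3 and Hdc were 7.19-fold and 6-fold lower, and Dmkn at least 5.55-fold. Papss2, F13a1, Anxa3 and Trem3 changed by log2 −2.53, −2.47, −2.41 and −2.37. Runx1 (0.64, adjusted p = 0.157), Kat6a (0.54, 0.111) and Nup98 (0.55, 0.101) did not pass.

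Of 27 LSK stem cell genes 21 rose (24 adjusted over the list alone), with a median of 1.56 (camera adjusted p = 3.82e-16, or 0.1004 with an estimated correlation). In the Hoxa list Hoxa5, Hoxa9 and Meis1 rose, also over the list alone (7 genes, 0.42, 0.00398, or 0.1004 estimated). Interferon response genes rose in 15 of 27 (17 over the list alone, 1.11, 2.78e-09, or 0.1004 estimated), with Gbp2 5-fold higher, Rtp4 at least 9.73-fold and Oasl2 at least 4.31-fold. Immediate early and stress genes rose in 12 of 22 (15 and 2 lower over the list alone, 1.40, 1.69e-04, or 0.464 estimated), with Egr1, Fos, Ier3 and Mcl1 at 3.23, 1.92, 1.60 and 0.93. Megakaryocyte and erythroid genes rose in 8 of 14, also over the list alone (1.11, 1.69e-04, or 0.208 estimated), with Car2 and Car1 10.9-fold higher. Wnt and beta-catenin targets rose in 5 of 7, also over the list alone (0.75, 0.00405, or 0.162 estimated), with Sox4 3.39-fold higher. JAK-STAT genes rose in 6 of 12 and fell in 1 (8 and 1 over the list alone, 0.68, 0.00612, or 0.113 estimated), with Socs3 at least 2.65-fold and Kit 2.39-fold higher and Il6ra lower. Of p53 targets Sesn1 and Trp53inp1 rose (15 genes, 4 over the list alone, 0.42, 0.0152, or 0.464 estimated, 0.053 with the mean of probe sets). Dendritic cell and MHC class II genes rose in 3 of 9 and fell in 1 (6 and 1 over the list alone, 0.73, 0.0191, or 0.318 estimated, 0.0696 within tag A), with H2-Aa and H2-Oa at 1.95 and 1.22 and Cst3 at −0.71.

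Of 16 primary granule genes 14 fell, also over the list alone (median −1.23, camera adjusted p = 1.12e-13, or 0.1004 with an estimated correlation), with Cst7 4.45-fold and Gstm1 3.36-fold lower. Monocyte genes fell in 9 of 19 (13 over the list alone, −0.82, 9.85e-07, or 0.258 estimated), with Irf8 and Ly86 at −1.62 and −2.16. G2 and mitosis fell in 6 of 35, also over the list alone (−0.38, 2.98e-06, or 0.464 estimated), with Cdca3, Racgap1, Aurka and Ube2c at −0.99, −0.85, −0.75 and −0.72. S phase fell in 4 of 30, also over the list alone (−0.14, 0.0124, or 0.598 estimated), with Rrm2, Cdc45, Tk1 and Mcm10. The mast cell, basophil and eosinophil list had Hdc lower among 7 (5 over the list alone, −0.90, 1.69e-04, or 0.1004 estimated). The ribosome biogenesis and Myc target list had Srm and Tfrc lower among 33 (0 over the list alone, −0.13, 0.0319, or 0.692 estimated). In the secondary granule list (17 genes, −0.23, 0.0319, or 0.598 estimated, 0.163 after quantile normalization) Ltb4r1, Pglyrp1 and Anxa1 fell and Padi4 rose, also over the list alone. The ATF4 list (24 genes, 2 higher and 4 lower, 2 and 5 over the list alone, −0.14, 0.038, or 0.484 estimated, 0.0524 with the mean of probe sets, 0.0859 after quantile normalization) had Sdf2l1, Xbp1 and Dnajc3 lower and Trib3 higher.

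Lists that did not pass for LSK were NF-kB (14 genes, 5 higher, 1 lower, also over the list alone, camera adjusted p = 0.110, and 0.0248 without GMP 2), cholesterol biosynthesis (19 genes, 4 higher, 1 lower, 5 and 2 over the list alone, 0.457) and glycolysis and hypoxia (24 genes, 3 higher, 4 lower, 4 and 5 over the list alone, 0.306, median −0.17 but mean 0.07). Ccl3 and Ccl4 rose and Ccl9 fell, Srebf2 rose and Fdps fell, and Ddit4 and Slc2a3 rose while Pgam1 fell. Myeloid transcription factors split, 5 of 20 higher with Gata2 at 1.59 and 5 lower with Cebpa at −1.14 and Gfi1 at −0.98 (7 and 5 over the list alone). Their median was 0.14 with a test direction of down (0.765). The lymphoid list had Cd27 and Dntt higher among 6 (2 and 1 lower over the list alone, 0.488, median −0.04 but mean 0.80). Of the sex-linked genes tested, Kdm5d and Eif2s3y, both on the Y chromosome and named after their values were seen, were higher by 0.90 and 0.84 among 3, too few for the list test. limma called 1734 probe sets (1300 genes), 1160 higher and 574 lower, or 66.9% higher, and after quantile normalization 1399 higher and 1383 lower, or 50.3%. The unadjusted p was under 0.05 for 3327 of 11452. The count was 765 without LSK 1, 867 without LSK 2, 1086 without LSK 3, 978 without GMP 1 and 2864 without GMP 2, and 1160 within tag A. Of the 85 named genes past the threshold, 61 kept the call with each array left out, 64 within tag A and 82 with the tag as a factor over all 24 arrays.

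The initiation program of the design joins the all-oncogene calls with the LSK filter. With 0 all-oncogene calls by limma it held 0 genes. The test of the design text gave 4 genes, against 167 in the design text. At an unadjusted p under 0.05 in both comparisons, a choice made after seeing the data, 244 genes had the same direction. With the 14-array mean of the oncogenes, also chosen after seeing the data, the program held 67 probe sets in 55 genes. Of 48 genes read by 1 probe set, 43 were called the same way in AE against GFP, 21 in MT2 against GFP and 4 in NHA9 against GFP. No gene was called for all 3, 20 for exactly 2, and 25 for AE only. Among the higher genes, the transcription factor gene Tcf4 differed by log2 1.20 (SE 0.13, adjusted p = 0.00123) and Nsmf by 1.15 (SE 0.18), each called for MT2 and AE. Sox4 was called for MT2 (at least 6.2-fold) and AE (at least 2.15-fold). Its GFP arrays lay under background, as they did for Meis1, so their mean differences have no exact size. Meis1 rested on MT2, as it was under background on every NHA9 and AE array. Ctla2b, at 1.55, rested on AE, with 3.90 there, 0.43 for MT2 (adjusted p = 0.332) and 0.34 for NHA9 (0.551). Prmt2, Tsc22d1 and Dbp were called for AE only. Among the lower genes were Sema4a (−1.26 for the oncogenes and −1.92 for LSK, adjusted p = 0.00471), Tmed3 (−0.89), the proton channel gene Hvcn1 (−0.84), Pilrb1 (−0.76), Prss16 (−0.68), the chaperone gene Hsp90b1 (−0.65), Nin (−0.63) and Rgcc (−0.60).

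By 1 probe set per gene, 116 genes were higher with the oncogenes and 670 higher in LSK among 6853, and 39 were both, where 11.3 are expected (odds ratio 4.90, 95% interval 3.22 to 7.36, Fisher's exact p = 1.15e-12). Lower in both were 9, where 1.15 are expected (odds ratio 13.2, Fisher's exact p = 6.54e-07), against 4 lower with the oncogenes and higher in LSK (2.05 expected). These comparisons share no array. All 55 program genes were called the same way for at least 1 single oncogene, which describes the arrays that chose them. In L-GMP 11 of the 55 were called the same way (with Sox4, Meis1 and Prmt2), but the LSK filter used the same GMP arrays. Without the LSK filter, 19 genes were higher with the oncogenes and in L-GMP, where 3.29 are expected (Fisher's exact p = 4.27e-10). Of the 21 genes lower with the oncogenes, 2 were lower in L-GMP (0.338 expected, Fisher's exact p = 0.0443) and 4 higher (0.612 expected).

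Among comparisons that share no array, AE and LSK went together most: r was 0.363 across genes, 181 genes were higher in both (57.8 expected, Fisher's exact p = 2.37e-51) and 50 lower in both (8.94 expected, 4.41e-25). Of the 1249 AE calls 653 stayed with the tag as a factor, and no overlap was run on that fit. On component 3 AE 2 to 4 lay above GFP (22.96 to 25.1 against −15.2 to −10.3), with AE 1 at −10.1. LSK likewise lay above GMP (8.75 to 22.6 against −56.6 to 5.84). Whether this component adds to the overlap was not tested. For MT2 and LSK r was 0.032, with 53 genes higher in both (54.8 expected, Fisher's exact p = 0.882) and 34 lower (10.8 expected, 1.53e-09), but 47 of the genes lower for MT2 were higher in LSK (17.9 expected). For NHA9 and LSK r was 0.259, and 6 of 8 higher genes were higher in LSK (0.741 expected, Fisher's exact p = 1.47e-05). With L-GMP, r was 0.113 for MT2 (42 genes higher in both, 18.9 expected, Fisher's exact p = 5.23e-07, and 9 lower, 3.06 expected, 0.00342). Against these, 12 genes lower for MT2 were higher in L-GMP (6.31 expected), and 10 higher for MT2 were lower there (9.19 expected). For AE r was 0.228 (61 higher in both, 19.3 expected, 6.36e-17, and 13 lower, 2.56 expected, 1.34e-06), with 8 lower for AE and higher in L-GMP (5.44 expected) and 13 the other way (9.09 expected). For NHA9 r was 0.217, and 3 of 9 higher genes were higher in L-GMP (0.279 expected, Fisher's exact p = 0.00214).

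L-GMP against GMP compared GMP of MT2 leukemias with their normal counterpart. Hoxa9 stood at 11.95 ± 0.12 (SD, n = 3) against 9.26 ± 0.50 (n = 4), 6.49-fold higher (log2 difference 2.70, SE 0.28, adjusted p = 0.000929). Meis1 rose at least 4.7-fold to 8.14 ± 0.15 (log2 2.27, SE 0.39, adjusted p = 0.0118), and Sox4 3.26-fold (adjusted p = 0.034). Igf2bp3, which MT2 had raised within 36 hours, was at least 23.4-fold higher (log2 5.71, SE 0.29, adjusted p = 3.76e-05). The acute phase gene Saa3 was at least 38.7-fold higher, the prostaglandin enzyme gene Hpgd at least 19.1-fold and Ms4a6d at least 13.4-fold. The troponin gene Tnnt1 was 28.6-fold higher (adjusted p = 6.1e-06), Sgip1 at least 12.7-fold, Slfn4 17.9-fold and Tctex1d1 at least 9.07-fold. Runx1 rose 2.38-fold to 8.95 ± 0.08 (log2 1.25, SE 0.29, adjusted p = 0.0435), while Kat6a (−0.23, 0.689) and Nup98 (0.12, 0.833) did not pass. Nkg7, a granule membrane protein, stood at 6.90 ± 1.10 against 11.82 ± 0.18, 30.3-fold lower (log2 −4.92, SE 0.44, adjusted p = 0.000413). The cyclin gene Ccnd2 was 10.5-fold lower and the stem cell factor receptor gene Kit 4.76-fold lower at 8.02 ± 0.27 (log2 −2.25, SE 0.27, adjusted p = 0.00229). Ccl9 and Pf4 were 13.8-fold and 15.5-fold lower, and Prg2 at least 9.38-fold. Ak4, Rab38 and Tiam1 were at least 4.86-fold, 4.81-fold and 5.69-fold lower.

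Values within tag A in what follows rest on L-GMP 1 as the only L-GMP array. Mast cell, basophil and eosinophil genes fell in 4 of 7 (7 adjusted over the list alone, median −1.85, camera adjusted p = 2.77e-08, or 0.166 with an estimated correlation), with Epx at least 1.71-fold and Prg3 at least 2.05-fold lower. Megakaryocyte and erythroid genes fell in 3 of 11, Pf4, Car2 and Icam4 (7 over the list alone, −1.06, 5.08e-06, or 0.317 estimated, 0.0633 within tag A). LSK stem cell genes rose in 7 of 20 and fell in 1 (11 and 2 over the list alone, 0.92, 1.21e-04, or 0.166 estimated), with the cell cycle inhibitor gene Cdkn1c at least 6.94-fold, Nkx2-3 at least 3.75-fold, Mycn 6.4-fold and Lmo2 2.37-fold higher. In the Hoxa list Hoxa9 and Meis1 rose (8 genes, 4 over the list alone, 0.73, 0.00369, or 0.166 estimated). Monocyte genes rose in 3 of 21, also over the list alone (0.77, 8.5e-04, or 0.352 estimated), with Csf1r 3.13-fold and Cd68 3.68-fold higher. The p53 targets Cdkn1a, Pmaip1 and Zmat3 rose (18 genes, 3 and 1 lower over the list alone, 0.36, 0.0118, or 0.352 estimated), Cdkn1a 3.91-fold. Immediate early genes rose in 4 of 22 (10 over the list alone, 1.06, 4.01e-06, or 0.352 estimated), with Egr1, Junb and Ier2 at 2.80, 1.07 and 0.93, and Klf2 at least 4.44-fold higher. Wnt targets Ccnd1 (5.33-fold) and Sox4 rose (6 genes, also over the list alone, 0.95, 0.0318, or 0.352 estimated, 0.242 within tag A). Cholesterol biosynthesis lay higher (19 genes, 0 called, also over the list alone, 0.38, 0.0154, or 0.492 estimated, 0.497 within tag A).

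Calls that did not hold without L-GMP 1 were the interferon response (30 genes, Oas1a and Mx1 higher, 9 over the list alone, median 0.78, camera adjusted p = 4.01e-06, or 0.352 with an estimated correlation, 0.0552 without it) and myeloid transcription factors (18 genes, 7 higher, also over the list alone, 0.88, 0.00322, or 0.352 estimated, 0.141 without it). There Cebpb rose 3.25-fold, Cebpd 3.04-fold and Spi1 1.88-fold. NF-kB had Bcl3 higher and Ccl9 lower among 16 (6 and 1 over the list alone, 0.56, 0.0259, or 0.352 estimated, 0.393 without L-GMP 1). JAK-STAT had Dusp6 and Socs3 higher and Kit lower among 14 (6 and 1 over the list alone, 0.53, 0.0141, or 0.352 estimated, 0.502 without L-GMP 1). S phase (30 genes, −0.23, 0.0141, or 0.668 estimated, 0.879 without L-GMP 1) and G2 and mitosis (35 genes, −0.31, 4.27e-04, or 0.618 estimated, 0.324 without L-GMP 1) had 0 called, also over the list alone. Primary granule genes lay lower, with Nkg7 and Gstm1 lower and Lyz2 higher among 16 (1 and 7 lower over the list alone, −0.50, 2.87e-04, or 0.352 estimated, 0.413 within tag A). Secondary granule genes had Anxa1 lower among 19, also over the list alone (−0.97, 0.0124, or 0.618 estimated, 0.0841 without GMP 2, 0.0882 after quantile normalization). Their direction was up with L-GMP 1 as the only L-GMP array. The ATF4 list had Asns, Cebpb and Nupr1 higher among 24, also over the list alone, with a median of −0.08, a mean of 0.11 and test direction down (0.972). Ribosome biogenesis and Myc targets passed only in other settings and in opposite directions, higher without L-GMP 1 (0.0297) and lower with it as the only L-GMP array (2.08e-06), where glycolysis and hypoxia passed as higher (0.037).

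limma called 556 probe sets for L-GMP (411 genes), 390 higher and 166 lower, or 70.1% higher, and after quantile normalization 426 higher and 285 lower, or 59.9%. The unadjusted p was under 0.05 for 2014 of 11439. The test of the design text called 15 (12 genes), with 1133 genes at an unadjusted p under 0.05, where the design text gives 2715 genes. The count was 257 without GMP 1, 269 without GMP 3, 357 without GMP 4, 1180 without L-GMP 1 and 211 without L-GMP 2. Of the 51 named genes past the threshold, 28 kept the call with each array left out and 48 with the tag as a factor over all 24 arrays.

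GFP GMP against GMP gives the background of infection and 36 hours in culture to the comparisons against GFP. Saa3 stood at 13.24 ± 0.08 (SD, n = 3) against 5.49 ± 0.14 (n = 4), at least 161-fold higher (log2 difference 7.75, SE 0.14, adjusted p = 1.06e-08). Mycn rose 87.4-fold to 13.41 ± 0.27 (log2 6.45, SE 0.30, adjusted p = 3.64e-06), the gene that each oncogene lowered against GFP. The cytokine feedback gene Socs3 rose at least 21.6-fold and Thbs1 at least 11-fold. Sox4, which MT2 and AE raised against GFP, fell at least 4.2-fold from 7.98 ± 0.44 to 5.27 ± 0.57 (log2 −2.71, SE 0.31, adjusted p = 0.000597). Cd34 fell 4.97-fold, Bex6 11.5-fold and Cd27 at least 3.47-fold. The heat shock genes Hspa1b and Hspa1a fell at least 18.2-fold and 9.75-fold. Hoxa9 (−0.06, adjusted p = 0.905), Runx1 (−0.63, 0.159), Kat6a (−0.19, 0.578) and Nup98 (−0.33, 0.161) did not pass.

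Of 25 glycolysis and hypoxia genes 22 rose, also over the list alone (median 1.61, camera adjusted p = 3.86e-19, or 0.109 with an estimated correlation), with Bnip3 21.6-fold, Ddit4 18.8-fold, Slc2a1 8.91-fold and Egln3 6.94-fold higher. Monocyte genes rose in 16 of 22 and fell in 1, the same over the list alone (1.36, 3.32e-11, or 0.109 estimated), with Lgals3 27.8-fold and Ctss 9.17-fold higher. Cholesterol biosynthesis rose in 14 of 19 (15 over the list alone, 1.18, 1.08e-10, or 0.186 estimated), with Msmo1 4.85-fold higher. The ATF4 list rose in 13 of 28 (17 over the list alone, 0.69, 1.76e-08, or 0.109 estimated), with Asns 6.21-fold higher and Nupr1 at least 4.43-fold. JAK-STAT genes rose in 8 of 16 and fell in 1 (9 and 1 over the list alone, 0.65, 1.01e-05, or 0.109 estimated), with Il4ra 3.19-fold higher. NF-kB genes rose in 6 of 15, also over the list alone (0.29, 7.11e-04, or 0.109 estimated), with Clec4e 7.87-fold higher. p53 targets rose in 8 of 18 (9 and 1 lower over the list alone, 0.47, 0.00134, or 0.188 estimated), with Cdkn1a 7.23-fold higher. Secondary granule genes rose in 9 of 20 and fell in 2 (10 and 3 over the list alone, 0.46, 0.00104, or 0.358 estimated), with Mmp8 40.6-fold higher and Camp 5.87-fold lower.

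Ribosome biogenesis and Myc targets fell in 22 of 33 and rose in 1 (26 and 1 over the list alone, median −0.84, camera adjusted p = 3.32e-11, or 0.227 with an estimated correlation), with Cad 3.01-fold, Ppan 2.87-fold, Nop2 2.41-fold and Utp20 2.38-fold lower. S phase fell in 12 of 30 and rose in 1 (17 and 1 over the list alone, −0.51, 1.78e-05, or 0.385 estimated), with Prim1 at −0.95. Mast cell, basophil and eosinophil genes fell in 6 of 7 (7 over the list alone, −1.89, 3.08e-07, or 0.109 estimated), with Cpa3 8.1-fold and Hdc 5.11-fold lower. Megakaryocyte and erythroid genes fell in 7 of 12 and rose in 1, the same over the list alone (−0.82, 0.00405, or 0.165 estimated), with Itga2b 2.82-fold lower. Cd27 and Ighm fell among 6 lymphoid genes (4 over the list alone, −0.70, 0.0248, or 0.165 estimated, 0.156 without GMP 2). LSK stem cell genes split, 3 of 16 higher with Tgm2 and 7 lower with Tal1, the same over the list alone (0.190, median −0.61 but mean 0.14). limma called 1782 probe sets (1295 genes), 938 higher and 844 lower, with 3383 of 11363 at an unadjusted p under 0.05. The larger side turned without GMP 2, with 1353 higher and 2690 lower, after quantile normalization, with 1356 higher and 1500 lower, and with array weights, with 2054 higher and 3120 lower. The count was 1108 without GMP 1, 4043 without GMP 2, 1113 without GMP 3, 894 without GFP 1, 811 without GFP 2 and 1062 without GFP 3. Of the 75 named genes past the threshold, 65 kept the call with each array left out and 74 with the tag as a factor over all 24 arrays.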

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

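The tests of the other ways to split the arrays and those on Xist were chosen after the results were seen, and those on the file-name tag of the AE arrays were set down before their own results were seen. Dixon's test at the 5% level was run within groups of 4 on 358 sets of values of the genes named and of array measures, and singled out an array in 27, where about 1 in 20 is expected by chance. AE 1 lay at −10.1 on component 3 (other AE arrays 22.96 to 25.1) and MT2 4 at 11.6 (others −3.67 to −2.54), each the array of its group with the other tag.

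In the AE group AE 1 was lower in Hsp90b1 (9.61 against 10.15 to 10.17) and Il7r (5.43 against 6.25 to 6.37) and higher in Sema4a (8.41 against 8.03 to 8.08). AE 3 was lower in Nin (7.15) and Nsmf (7.96) and higher in Ppp1r15a (7.85). In the GMP group 7 of 12 such genes pointed to GMP 2: Aurka (8.69), Car2 (7.43), Cd68 (7.10), Il6ra (6.53) and Prmt2 (4.78) were lower there, and Ccl3 (7.85) and Ier2 (9.80) higher. GMP 1 was higher in Anxa1 (12.00) and Tfrc (9.57), GMP 4 in Cebpd (8.30) and Tiam1 (9.10), and GMP 3 was lower in Tnnt1 (5.88). In the MT2 group MT2 4 was higher in Ankrd28 (10.45), Hvcn1 (7.72) and Kat6a (7.97), MT2 3 was lower in Gins1 (7.83) and higher in Prss16 (6.28), MT2 2 was lower in Bex6 (7.98) and MT2 1 in H2-Oa (5.56).

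Splitting the arrays of a comparison in all other ways (for all oncogenes in 100 of 364 ways) shows whether other groupings give as many calls. With at most 35 splits in the other comparisons, and a look at each, being the highest does not exclude chance. Splits that mix the groups also hold the real difference in their spread, which can lower their counts. The real grouping alone reached its count for MT2 against GFP (1 of 35, 1316 probe sets, and the highest other 276) and for LSK against GMP (1 of 35, 1734 against 0). So it did for L-GMP against GMP (1 of 35, 556 against 0), MT2 against NHA9 (1 of 35, 828 against 112) and MT2 against AE (1 of 35, 3227 against 25). For GFP GMP against GMP the real grouping was the highest (1 of 35), but with 1782 against 1775 for GMP 2 joined to the GFP arrays. For NHA9 against GFP there are too few splits (1 of 10, 22 against 0). Chance can be excluded even less for all oncogenes against GFP, where 18 of 100 splits reached the 1250 probe sets at an unadjusted p under 0.05. The highest of those run, 3347, set AE 2 to 4 apart from the rest, which points to a structure of the samples. These arrays share tag B, but MT2 4 has it too and lay on the other side, so the split follows AE as well as the tag. Nor can it be excluded for AE against GFP (2 of 35, 1249 against 1344 for AE 1 joined to GFP, which is exactly tag A against tag B) or for NHA9 against AE (3 of 35, 813 against 2993 for AE 1 with NHA9 1 and NHA9 2, the tag A arrays, against the rest). Within tag A AE is 1 array, so that fit does not bear on chance.

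The AE calls lie along the tag, since all GFP arrays have tag A and 3 of 4 AE arrays tag B, and if the tag alone made them AE 1 would not share them. Over the 3045 probe sets called for AE 2 to 4 against GFP, AE 1 lay the same way from the other tag A oncogene arrays on 66.6%, where those arrays lay so on 40.2% to 46.3%, which argues against the tag alone. A tag effect on top of an oncogene effect fits, since in the direction of the AE change MT2 4 lay by a median of 0.16 from MT2 1 to 3 and GMP 4 by 0.353 from GMP 1 to 3, where the highest tag A arrays lay at 0.0148 for MT2 and 0.271 for GMP. Over all 24 arrays in 1 fit 969 of the 1249 calls stayed (1000 of 1259 higher). With the tag as a factor 653 stayed (559 of 1309 higher). The calls and their balance thus depend on how the tag is handled, and the share due to it in each gene stays open, since that fit assumes the same tag effect in all groups.

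Xist, which is made only in cells with an inactive X chromosome, stood at 11.71 on NHA9 1 and at 5.37 to 6.64 on the other 23 arrays. All 3 of its probe sets were highest on that array, which argues against a fault of 1 probe set. Both Y-linked genes measured were lower there than on each other transduced array: Eif2s3y at 8.05 (−1.24 from their median) was not lost, and Kdm5d at 5.36 (others 5.79 or higher) was under the background of 5.91. On GMP 2, which was not transduced, Eif2s3y and Kdm5d were also low (8.39 and 5.38) with Xist at 6.27, so low values of both occur without high Xist. RNA of female cells mixed into the NHA9 1 sample could give the values of that array. Whether such a mixture moved the NHA9 comparisons is open, as is the sex of the animals, and without this array 1 probe set was called against GFP.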

How the results depend on the processing

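The mean of the 3 oncogenes in 14 arrays and the program at unadjusted p were chosen after the results were seen, and the other alternatives were set before. Counts below are of probe sets past the threshold unless genes or lists are named, and the cause of a change was not tested.

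Fitting all 24 arrays together gave 51 for all oncogenes, 190 for MT2, 7 for NHA9 and 2006 for L-GMP. With the tag as a factor as well, these were 25, 303, 13 and 1969, with 2997 for LSK and 2719 for GFP GMP. For AE it was 1309 (559 higher). Calls kept with the tag rest on the joint fit too. Within tag A alone the counts were 196 for NHA9, 1891 for AE, 186 for L-GMP and 2091 for MT2 against NHA9, where AE and L-GMP are 1 array each and their counts are no check of the group. With the opening letter or number of the file name as a block they were 38 for NHA9 and 919 for LSK. A fit of only the 2 groups gave 297 for NHA9 against AE.

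The test named in the design text gave 116 for all oncogenes, 0 for MT2, 0 for NHA9, 0 for AE, 268 for LSK, 15 for L-GMP and 606 for GFP GMP. Array weights gave 1007 for all oncogenes, 2671 for MT2, 2400 for NHA9 and 4373 for AE. They gave 4519 for LSK, 5485 for L-GMP and 5174 for GFP GMP. Quantile normalization gave 2782 for LSK and 2856 for GFP GMP, and the mean of the 3 oncogenes 217. Dropping the filter left every count within 1.5-fold, as did raising values under 60 to 60, which was not run between oncogenes, while folds of genes near background remain lower bounds.

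With replicate number as a block the counts were 1 for NHA9, 399 for AE, 346 for L-GMP and 542 for MT2 against NHA9. Correlations of same-numbered arrays there ran from −0.17 to 0.10 for NHA9 and −0.29 to −0.09 for AE. They ran from −0.28 to 0.12 for L-GMP and −0.04 to 0.17 for MT2 against NHA9.

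Leaving out each array in turn gave ranges of 0 to 0 for all oncogenes, 170 to 1607 for MT2, 1 to 202 for NHA9, 329 to 3061 for AE, 765 to 2864 for LSK, 211 to 1180 for L-GMP and 811 to 4043 for GFP GMP. Between oncogenes the ranges were 221 to 1037 for MT2 against NHA9, 2392 to 3307 for MT2 against AE and 388 to 1372 for NHA9 against AE. Of 8018 alternative fits of named genes 6857 left the outcome as it was, which includes uncalled genes that stayed uncalled. A call was lost in 1136 and gained in 25, and the direction turned in 0 where either fit had a call.

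The initiation program, with 0 genes, held 19 with all 24 arrays, 10 with the tag as well, 4 by the test named in the design text and 211 with array weights. With the mean of the 3 oncogenes it held 55 genes, with 55 program genes called for a single oncogene and 11 program genes called in L-GMP. At unadjusted p in both comparisons it held 244, and these numbers were 168 and 21. Without any 1 array it stayed at 0.

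With an estimated correlation the number of lists called fell to 0 in each comparison. It had been 6 for all oncogenes, 8 for MT2 and NHA9, 9 for AE, 17 for LSK and L-GMP and 13 for GFP GMP. Between oncogenes it had been 8 for MT2 against NHA9 and 9 for MT2 against AE and NHA9 against AE. The list results thus rest on the preset correlation of 0.01. The estimated one is drawn from the few arrays of a comparison. The loss of calls therefore cannot tell genes of a list that vary together from a test with too little power.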

Other observations

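The pattern below was noticed in the data, and the tests on the shared GFP arrays and the tag were set down before their own results were seen. MT2 fold changes against GFP ran opposite to the change from fresh to GFP GMP, with r = −0.52 over 7364 genes. The shared GFP arrays alone would give such a value, but with NHA9 against GMP, which shares no array with MT2 against GFP, r was still −0.398, and within tag A it was −0.399. On component 1 the MT2 arrays differed from the other transduced arrays by −17.8, toward fresh GMP, looked at because it was seen. MT2 may thus hold back part of the change that infection and culture bring, or MT2 cells may have been infected or sorted at another state. A time course of GFP and MT2 cells from the same culture would tell these apart.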
